A study of Homo sapiens with 6 samples.

How the data were processed

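RNA from 6 libraries of HT-1080 cells was compared, grouped as in the labels. Of these, 3 were treated for 48 h with 20 μM PhenDC3 in 1% DMSO and 3 with 1% DMSO alone. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit from poly(A) RNA. The submitters' processing notes name CASAVA, TopHat2 2.0.11, Cufflinks 2.2.1, Cuffdiff, STAR 2.7, featureCounts, DESeq2 1.18.1 and the build hg19, without saying which step used which tool. The annotation, filters and strand setting of the counting are not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

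The deposited table lists 22925 genes. Its 6 columns of per-library signal are gene read counts that the authors divided by 1 size factor per library, as the values show. In every column 100% of the values were whole multiples of the smallest value above 0, within a relative tolerance of 1e-06, so whole reads could be recovered. They summed to between 7371056 and 14292987 per library. The authors' deposited log2 fold change is of PhenDC3 over DMSO. The authors' deposited adjusted p-value is missing for 1332 genes, which had mean values of 1.07 or less. DESeq2 run here on the recovered reads called the same 8418 genes as the deposited table, none being called in one alone. The largest difference in log2 fold change was 0.0051 and in adjusted p 0.27. Symbols were in the table for 15630 genes and were completed from reference tables to 22142. GENCODE release 29, on GRCh38, was used only for gene types, overlaps between genes, span lengths and transcript sequences, and matched 22123 genes. None of its coordinates are printed.

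The design fixed before the data were examined gave edgeR for counts and limma for normalized values. As the table holds normalized values, the main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with empirical Bayes moderation and no replicate block. Genes with a mean normalized count of 5 or more were tested, 16482 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount lowers the fold change of low genes. The minimum mean of 5 and a variance trend on the mean were chosen after the values, and counts of calls with and without them, had been seen. Alternatives were planned or added as stated in the closing section, including edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. edgeR tested 14984 genes and called 9437.

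The 26 gene lists were fixed before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 26 lists. The test was repeated with an estimated correlation, and fry was run beside it. With an estimated correlation camera also rests on the 4 residual degrees of freedom, unlike at the preset one. Named genes followed a rule fixed at the same time. It takes the 10 largest rises and 10 largest falls among called genes with a mean of 100 or more and a gene symbol that is not a clone, antisense or pseudogene name, 13 genes fixed by name, and up to 4 called members of each list with the smallest adjusted p. List members that moved against their list, the mitochondrial genes that did not pass and the cell type markers singled out were named after their values were seen. Some genes the rule takes, and 1 list, are not reported here. Heme, NRF2, cholesterol, lysosome and the other lists were written from general knowledge of these pathways.

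A planned test of G quadruplex motifs around transcription start sites was not run, because it needs genome sequence, which was not used here. In its place, an annotated transcript of each gene was searched in its first 200 bases. This was the longest coding transcript, or the longest of any type where a gene had none. The motif sought was 4 runs of 3 or more G with loops of 1 to 7 bases.

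Libraries of a group differed beyond sampling noise, with a chi-square per degree of freedom of 1.45 to 7.75, so none was treated as a duplicate. The largest values were between DMSO replicate 3 and the other DMSO libraries. Limma was tested on simulated reads of 16496 genes, with each gene's mean over all 6 libraries and the depth of each library. In it 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold. Limma recovered 71.6% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 90.9% of those changed 4-fold, with 5 false calls among 164. These shares need not hold for the data, where 59.6% of tested genes were called and the adjustment is therefore less strict. The list test gave p under 0.05 for 1 of 99 unchanged lists. The simulated genes were drawn independently, so this does not show how the test behaves for lists whose members move together. In the data the estimated correlation within a list was as high as 0.759. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Bootstrap intervals, at the 95% level, used 2000 resamples, and 20000 for the comparison of pairs with any shared exonic base. The version with 100 or more shared bases kept 2000. The comparison of overlapping pairs was first run with 2000 resamples and a minimum of 100 shared exonic bases, neither part of the rule written beforehand, and its lower bound then lay just under 0. The rule as written, any shared base, was then run with more resamples.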

Results

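The series measured poly(A) RNA by sequencing in HT-1080 cells, an established human fibrosarcoma line, after 48 h with PhenDC3 or with solvent alone. PhenDC3 is a small molecule that binds and stabilizes G quadruplexes, the stacked 4-stranded structures that guanine-rich DNA and RNA can form. It was given at 20 μM in 1% DMSO, and the control cells received 1% DMSO alone, with 3 libraries in each group. The normalized values, turned back into whole reads, came to between 12574952 and 14292987 reads per DMSO library. The PhenDC3 libraries were shallower, at 7371056 to 9386691 reads. The comparison asks which transcripts change in abundance, relative to the other transcripts, when the ligand is present. Values below are read counts divided by the authors' size factor, given as mean ± SD over 3 libraries, and fold changes on the log2 scale are of the value plus 1. The deposited table gives no positions, so genes are placed by chromosome only.

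A majority of the tested genes differed between the groups. Of 16482 genes tested, 9818 (59.6%) changed in limma at an adjusted p under 0.05, 4806 of them higher and 5012 lower. The median log2 change of the tested genes was -0.0168. Scaling each library by a size factor hides a shift shared by all genes, so similar numbers of rises and falls are partly built in. The changes were mostly small, since 1627 genes were higher and 1065 lower by 2-fold or more, and 432 and 90 by 4-fold or more. In 64.1% of tested genes the 3 PhenDC3 libraries did not overlap the 3 DMSO libraries, against 10% by chance. The first principal component held 78.3% of the variance. Pearson's r between libraries, across genes, was 0.987 or more within a group and between 0.944 and 0.947 across groups. By the authors' deposited table, genes higher numbered 4250 and genes lower 4168 at the same threshold, and 8134 genes were called in both, all with the same sign.

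Heme oxygenase and ferritin transcripts rose. HMOX1 (ENSG00000100292, chromosome 22), which encodes the enzyme that breaks down heme, rose 29.2-fold, from 160 ± 17.8 to 4670 ± 149 normalized counts (limma, log2 fold change 4.86, SE 0.08, adjusted p = 1.68e-20). The ferritin genes FTH1 and FTL, whose products store iron, rose 6.90-fold and 4.75-fold, and FTL reached 101302 ± 5902 normalized counts. Both have processed pseudogenes that rose by similar amounts, with a median log2 change of 2.65 over 12 copies of FTH1 and 2.29 over 2 copies of FTL, so how reads were divided among the copies is uncertain. SLC25A28, a mitochondrial iron importer, rose 2.62-fold from 152 normalized counts. SLC25A37, the other mitochondrial iron importer of the list and more abundant, fell from 1643 to 1208, or 0.736 of its DMSO level. TFRC, the transferrin receptor, fell to 0.771 of its DMSO level. The list of heme degradation and iron genes as a whole went both ways, with 9 of 22 tested members higher and 7 lower, and did not pass the list test (limma camera, adjusted p = 0.0963). It passed when ranked by log2 fold change (adjusted p = 0.0305) but not with an estimated correlation (adjusted p = 0.252). In heme synthesis 2 of 11 genes were higher, among them ALAS1, the first enzyme of the pathway, at 1.59-fold. The other, SLC25A38, was 1.30-fold higher, and 5 members fell, UROS among them (camera, adjusted p = 0.527).

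Targets of the antioxidant regulator NRF2 rose with HMOX1. Of 26 tested, 18 were higher and 3 lower (camera, adjusted p = 1.13e-06, and adjusted p = 0.0542 with an estimated correlation). OSGIN1 rose 13.5-fold, GCLC, which makes the first step of glutathione synthesis, 3.59-fold, ABCC3, an export pump, 3.87-fold, and NQO1, a quinone reductase, 2.43-fold. The 3 that fell were PGD, TALDO1 and ABCC1. Metallothionein and zinc export genes were few at this depth, with 3 of 4 tested higher, SLC30A1 1.71-fold and MT1X 2.19-fold (camera, adjusted p = 0.0897). The third, MT2A, was 1.16-fold higher and lost its call in 4 of the 6 fits that left out 1 library. Without DMSO replicate 3 the list passed (adjusted p = 0.0222), while with all libraries it had an adjusted p = 0.387 with an estimated correlation.

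Lysosome and autophagy genes rose as a group, 28 of 31 tested being higher and none lower (camera, adjusted p = 1.79e-12, and adjusted p = 0.0542 with an estimated correlation). SQSTM1, the autophagy receptor p62, rose 12.9-fold, from 2966 ± 105 to 38185 ± 2237 normalized counts. GPNMB, a lysosomal glycoprotein, rose 7.80-fold, GABARAPL1, an autophagosome protein, 5.20-fold, and NPC1, which carries cholesterol out of lysosomes, 3.22-fold. The genes of cholesterol synthesis and uptake went the other way. Of 24 tested, 23 fell, and TM7SF2 alone rose (camera, adjusted p = 3.3e-13). This was the one list of the 26 that also passed with an estimated correlation (adjusted p = 0.0278). HMGCS1, an early enzyme of the pathway, fell to 0.278 of its DMSO level and FDFT1 to 0.280.

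**Figure D1:**
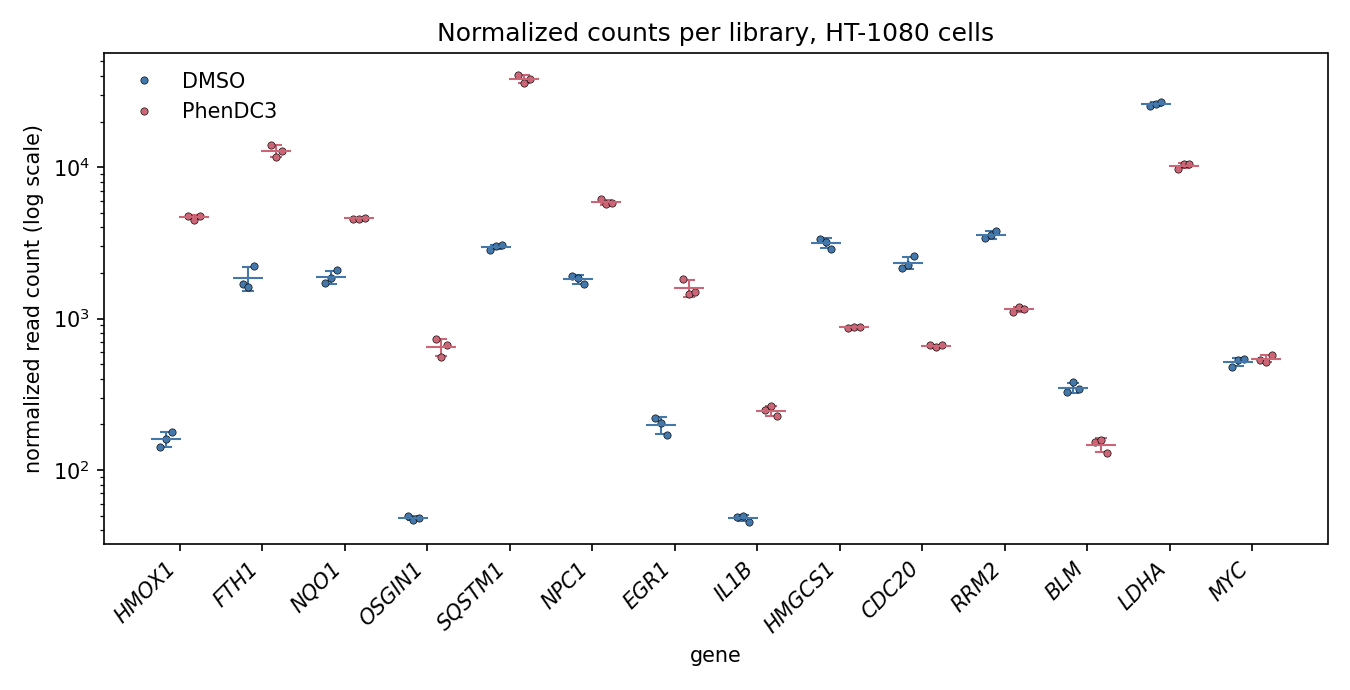
Normalized read counts (vertical axis, log scale) of 14 genes in the 3 DMSO (blue) and 3 PhenDC3 (red) libraries. Each dot is a library, the wide dash the mean and the bar 1 SD on either side. HMOX1 lies near 160 in DMSO and 4670 in PhenDC3, SQSTM1 near 2966 and 38185, and MYC near 518 and 542 with overlapping libraries.

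Genes of the cell division cycle fell. All 29 genes of the mitosis list were lower (camera, adjusted p = 2.02e-18, and adjusted p = 0.0542 with an estimated correlation), among them CDC20 at 0.284 of its DMSO level and KIF20A at 0.286. In the list for DNA replication and entry into S phase, 29 of 33 genes were lower and CCNE1, cyclin E1, was higher (camera, adjusted p = 1.47e-12, and adjusted p = 0.12 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell to 0.323. Genes of homologous recombination and the Fanconi pathway followed, with 19 of 23 lower and PALB2 higher (camera, adjusted p = 6.6e-07, and adjusted p = 0.0542 with an estimated correlation). UBE2T fell to 0.310 and EXO1, a nuclease, to 0.449.

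The cell cycle inhibitor CDKN1A, a gene fixed by name beforehand, rose 1.54-fold. Among the 10 largest falls were TENM2, which was 8.38-fold lower, RGS4, PLXNA4, ARHGDIB, CDKN2C, MPP4, COL13A1, PAPPA2 and NTM, the last 5.16-fold lower. CDKN2C encodes a cyclin-dependent kinase inhibitor and COL13A1 a transmembrane collagen.

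Of the proteins known to unwind or bind G quadruplexes, 14 of 24 genes were lower and 3 higher (camera, adjusted p = 0.0278, and adjusted p = 0.301 with an estimated correlation). The call was also lost with a preset correlation of 0.05 (adjusted p = 0.114). The helicase BLM fell to 0.418 and DNA2 to 0.501, while ERCC2, ERCC3 and REV1 rose. Genes whose promoters are described in the literature as holding a G quadruplex did not move one way, as 6 of 17 were higher and 7 lower (camera, adjusted p = 0.945). The list's median log2 change was 0.03, its mean -0.21, and its test pointed down. VEGFA rose 1.26-fold, RB1 fell to 0.514 and TERT to 0.461. MYC was at 518 ± 34.9 and 542 ± 29.6 normalized counts (limma, log2 fold change 0.07, SE 0.08, adjusted p = 0.485). KIT, at 0.69 to 5.41 normalized counts in DMSO and 0 to 1.49 in PhenDC3, was too low to be tested. In the telomere list 2 of 13 genes were higher and 6 lower (camera, adjusted p = 0.368). TERF2, which binds telomeric DNA, rose 2.26-fold and STN1 fell to 0.465.

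**Figure D2:**
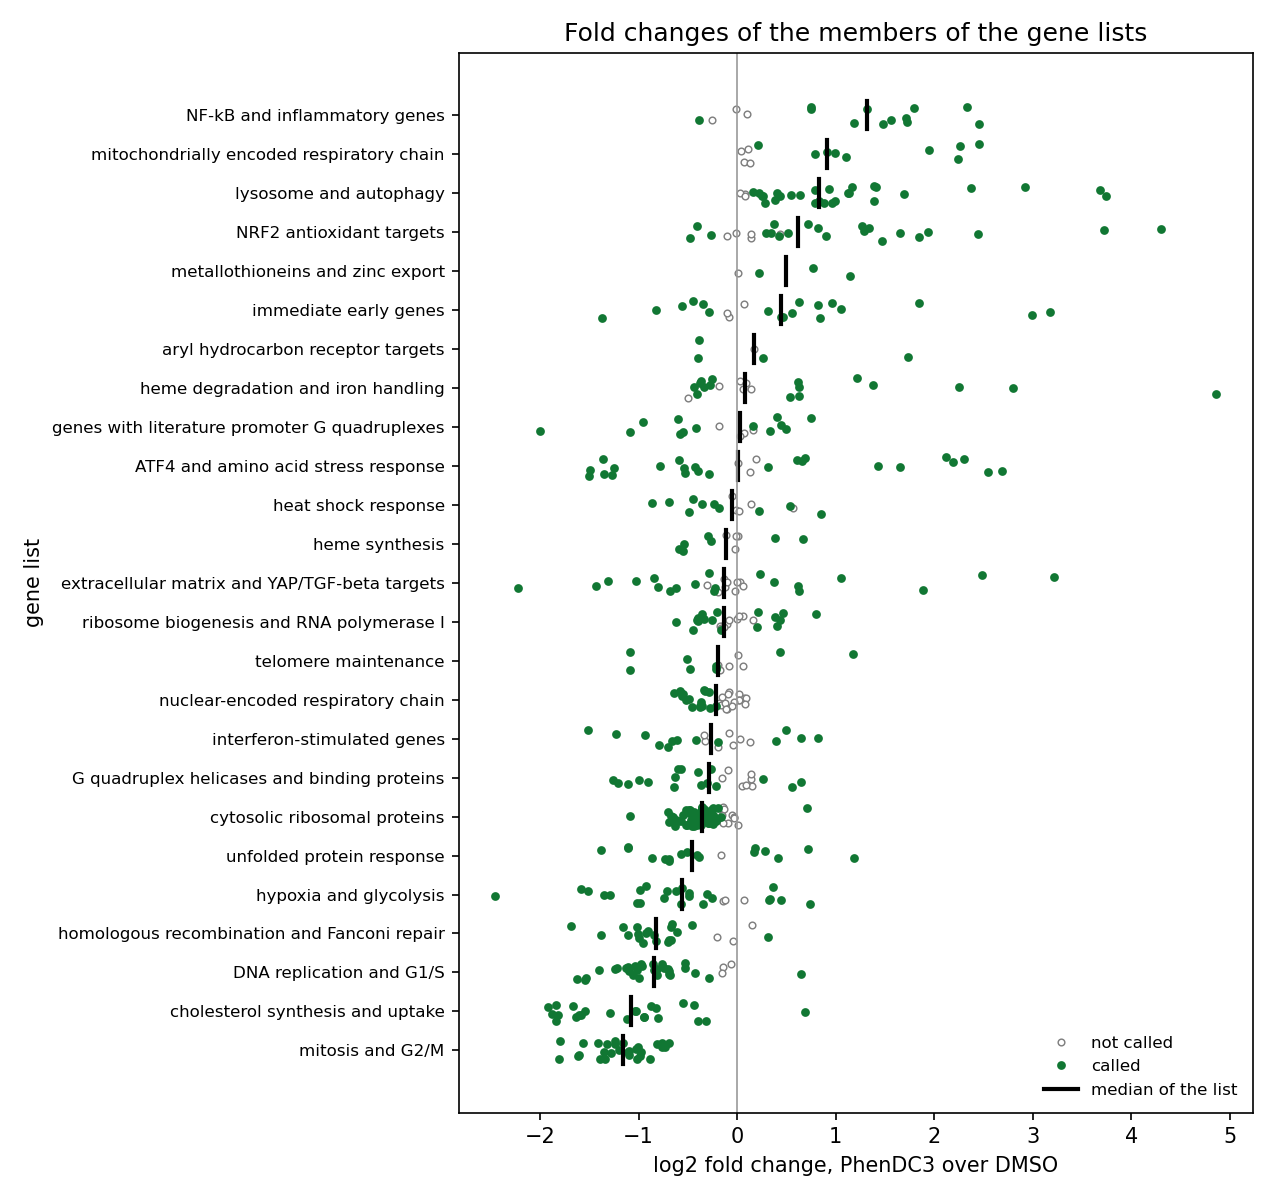
Log2 fold change of PhenDC3 over DMSO (horizontal axis) for every tested member of the gene lists reported here (vertical axis), ordered by median. Filled dots are genes called by limma, open dots genes not called, and black bars list medians. The medians run from -1.15 for mitosis to 1.32 for inflammatory genes.

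RNA from the mitochondrial genome took a larger share of reads, 15.4% ± 0.05 in PhenDC3 against 3.87% ± 0.13 in DMSO. Its rRNA accounted for most of the difference, at 8.22% ± 0.036 against 0.269% ± 0.013. RNR1 (ENSG00000211459), the 12S rRNA, rose 66.3-fold, from 5519 ± 349 to 365807 ± 2948 normalized counts (limma, log2 fold change 6.05, SE 0.06, adjusted p = 8.11e-24), and RNR2, the 16S rRNA, 25.8-fold. All 20 mitochondrial tRNA genes tested were higher, by 1.75 to 5.27 on the log2 scale. Of the 13 protein-coding genes 9 were higher and none lower (camera, adjusted p = 6.6e-07, and adjusted p = 0.0542 with an estimated correlation). CYTB rose 5.49-fold and ND5 4.74-fold, while COX3 (log2 0.13), ATP6 (0.11), ND2 (0.07) and ATP8 (0.04) did not pass. The nuclear genes of the respiratory chain were lower in 17 of 33 cases and higher in none (camera, adjusted p = 0.00277, and adjusted p = 0.535 with an estimated correlation). Their median log2 change was -0.22, and ATP5O fell to 0.639. The list was not called when ranked by log2 fold change (adjusted p = 0.131).

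**Figure D3:**
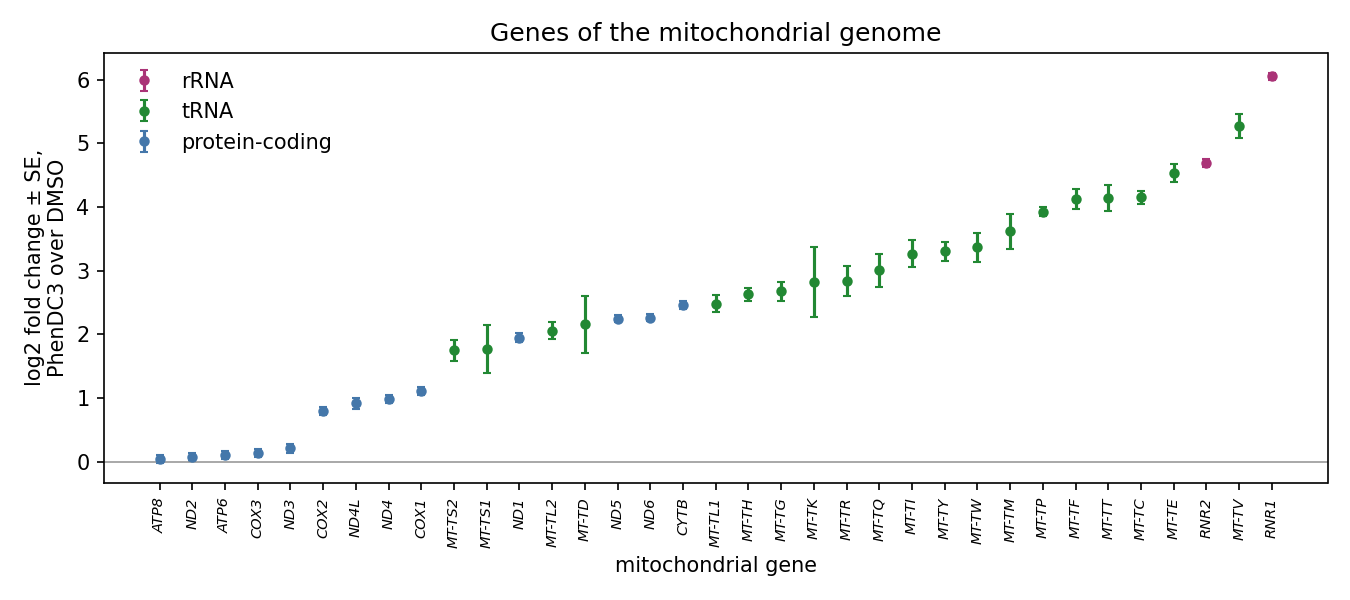
Log2 fold change ± SE of PhenDC3 over DMSO (vertical axis) for each tested gene of the mitochondrial genome (horizontal axis), from 3 libraries a group. The 2 rRNA genes (purple) lie at 4.69 and 6.05, the 20 tRNA genes (green) between 1.75 and 5.27, and the 13 protein-coding genes (blue) between 0.04 and 2.46.

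The other large rises mixed clear and uncertain cases. ARC, an immediate early gene, rose 43.5-fold from 9.68 ± 0.42 normalized counts. RPL3L had 10 reads in DMSO and 511 in PhenDC3, a ratio of 90.3 (95% exact interval 48.7 to 190), and ARL14EPL 14 and 613, a ratio of 77.4 (45.8 to 142), with intervals for counting error only. MRNIP rose 35.7-fold, but it shares 1582 exonic bases with SQSTM1 on the opposite strand, and how the counting treated strand is not given in the sources used here. The gene listed as MTRNR2L2, which GENCODE names MTRNR2L12, rose 30.01-fold and is a nuclear copy of the mitochondrial 16S rRNA, so its value is uncertain. The mitochondrial tRNA genes MT-TV and MT-TE were also among the 10 largest rises.

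Inflammatory genes under NF-kB rose in 11 of 15 cases, CXCL8 being lower (camera, adjusted p = 0.000247, and adjusted p = 0.0542 with an estimated correlation). IL1B rose 5.14-fold, SOD2 3.28-fold and LIF 2.95-fold. Of 21 immediate early genes 12 were higher and 6 lower (camera, adjusted p = 0.0278, and adjusted p = 0.447 with an estimated correlation), and the call was lost when ranked by log2 fold change (adjusted p = 0.076). EGR1 rose 7.97-fold and NR4A1 9.35-fold. Interferon-stimulated genes gave 4 higher and 9 lower of 20 (camera, adjusted p = 0.322), with OAS3 at 0.573 of its DMSO level. For aryl hydrocarbon receptor targets, 2 of 5 were higher, CYP1A1 and AHR, and 2 lower, SLC7A5 and TIPARP (camera, adjusted p = 0.988). AHR lost its call without PhenDC3 replicate 3 (adjusted p = 0.0718).

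Stress pathways of the endoplasmic reticulum were divided. In the unfolded protein response list 11 of 18 genes were lower and 6 higher (camera, adjusted p = 0.0278, and adjusted p = 0.193 with an estimated correlation), and the call was lost when ranked by log2 fold change (adjusted p = 0.142). The chaperones PDIA4 and HSP90B1 fell to 0.385 and 0.465. The ATF4 list had 11 of 27 genes higher and 13 lower (camera, adjusted p = 0.945), with a median log2 change of 0.01 and a test pointing down. Its 4 members with the smallest adjusted p were all rises, among them DDIT3, which encodes CHOP, at 5.85-fold, ATF3 at 4.59-fold and PPP1R15A at 4.36-fold. Of the amino acid synthesis genes, named after their values were seen, ASNS fell to 0.351, PHGDH to 0.355 and PSAT1 to 0.392. Heat shock genes were 3 higher and 7 lower of 15 (camera, adjusted p = 0.376), HSPA1A at 1.80-fold and HSPD1 at 0.618.

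Genes of hypoxia and glycolysis fell in 19 of 27 cases and rose in 5 (camera, adjusted p = 3.79e-05, and adjusted p = 0.0542 with an estimated correlation). LDHA fell to 0.393 of its DMSO level, PGK1 to 0.408 and ALDOC to 0.332. Cytosolic ribosomal protein genes moved little but together, with 66 of 77 lower, RPS28 higher and a median log2 change of -0.36 (camera, adjusted p = 1.02e-10, and adjusted p = 0.447 with an estimated correlation, which was 0.759). RPL12 fell to 0.469. Ribosome biogenesis genes were 7 higher and 10 lower of 27 (camera, adjusted p = 0.59), RRP12 at 1.74-fold and FBL at 0.650. Extracellular matrix genes and targets of YAP and TGF-beta were 8 higher and 12 lower of 29 (camera, adjusted p = 0.35). The collagenase MMP1 rose 9.77-fold, while the basement membrane collagens COL4A1 and COL4A2 fell to 0.403 and 0.492.

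With 14 lists past the preset-correlation test, 5 higher and 9 lower, the list calls depend on that correlation, and 1 remained with an estimated one. The counts of members adjusted over the list alone were the same as those over all genes in 19 of the 26 lists. In limma's fry test 22 lists moved one way on balance and all 26 changed in either direction. That test asks whether members changed at all, not whether they changed more than other genes. With 59.6% of all tested genes called, almost any list was likely to pass, so it does not set these lists apart. Of markers for cell types other than mesenchymal, 4 were tested. ELF3 was higher, at 10.6 against 0.26 normalized counts, and CD68 at 15.4 against 5.98, while CLDN4 and EGFL7 did not pass. Among 6 mesenchymal markers COL1A1 was higher and 4 were lower, including VIM, at 13620 against 25153 normalized counts.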

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

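The tests with edgeR at its default scaling, the authors' deposited table, no variance trend, edgeR without mitochondrial genes and thinned reads were chosen after seeing the data. The limma count of 9818 genes stayed within 1.5 times under every alternative run except a fold minimum. It ranged from 8058 at an adjusted p under 0.01 to 10801 at 0.1, and from 8965 to 9564 when 1 library was left out. With reads thinned to 7371056 per library 9063 genes were called, with no variance trend 8936, and with DESeq2 8418. Requiring a log2 fold change of 1 or more left 2692 genes, 1627 higher and 1065 lower, by its own construction. Every gene called both in the main test and in any of these fits had the same sign in both.

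With an estimated inter-gene correlation 1 gene list passed, 0 higher and 1 lower, against 5 and 9 at the preset correlation. At an unadjusted p under 0.05 limma's camera gave 4 higher and 5 lower with the estimated correlation. When 1 library was left out, 14 to 15 lists passed. Of values for the 127 genes the naming rule takes, 757 of 762 kept their call and sign when 1 library was left out, and 1513 of 1516 did under the other settings. Those that did not were MT2A and AHR. No result changed direction with a call. The residuals gave little sign that the replicate numbers pair the libraries: the correlations of same-numbered residuals were 0.008, 0.071 and 0.027. With 3 libraries a group this cannot settle whether same-numbered libraries were made together. With the replicate number as a block 10155 genes and 15 lists were called, the added list being heme degradation and iron handling (adjusted p = 0.029).

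The promoter motif test and its alternatives were not run. On simulated reads, with far fewer genes changed than were called in the data, limma recovered 71.6% of genes changed 1.5-fold. Some changes of that size can thus go undetected, but the share missed in the data is not known. Recovery was not split by expression.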

Other observations

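The tests of poly(A) selection, of library scaling, of tRNA genes with their neighbours, of their spread without estimation error and of MRNIP against SQSTM1 were chosen after their results had been seen in part, and the transcript motif test after the values had been seen.

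RNA classes other than mRNA moved apart. Among protein-coding genes 30.8% were higher and 34.3% lower in limma. Of 580 long intergenic RNA genes tested, 227 (39.1%) were higher and 66 (11.4%) lower. Of 776 antisense genes 238 (30.7%) were higher and 82 (10.6%) lower, so they differed from protein-coding genes in fewer falls and not in more rises. Antisense values are uncertain, since the strand setting of the counting is not given in the sources used here. Processed pseudogenes went the other way, 142 (8.9%) higher and 461 (29%) lower of 1592. They differed from protein-coding genes in fewer rises and not in more falls. Across 1038 processed pseudogenes with a tested parent gene, Spearman's rho with the parent's log2 fold change was 0.709. That is a relation across genes, which are not independent, and shared reads would give it too. Of 13 replication-dependent histone genes 7 were higher and none lower, with a median log2 change of 0.44. Of 43 small RNA genes (snoRNA, snRNA, scRNA and others) 5 were higher and 8 lower, with a median of -0.10, and 25 of these were snoRNA genes, 1 higher and 6 lower. HIST1H1C rose by 1.82 and HIST1H4H by 1.90 on the log2 scale, genes singled out after their values were seen.

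Mitochondrial rRNA and tRNA genes rose further than most mitochondrial mRNA. Scaling cannot move a ratio within a library, and the log2 ratio of RNR1 to COX3 was higher in PhenDC3 by 5.92. Precursor RNA left uncut throughout was predicted to raise the tRNA genes by the same fold. Their log2 changes had an SD of 0.958 (95% bootstrap interval 0.68 to 1.17), and of 0.93 (0.62 to 1.15) with the error of the estimates taken off. The tRNA genes thus did not share a common fold, but this spread cannot decide about uncut RNA. Equal added amounts would give unequal folds, since DMSO means of these genes ran from 0.517 (MT-TK) to 249 (MT-TP) normalized counts. Weaker poly(A) selection stays open: 56 histone and small RNA genes had a median log2 change of -0.03 (95% bootstrap interval -0.17 to 0.14), but 42 of them had means under 20, and the 7 with means of 50 or more had a median of 0.81 (0.04 to 1.56). Apart from BCYRN1, a small RNA gene, these 7 were histone genes, so they do not show small RNA genes at higher abundance. That the RNAs of the 56 genes lack a poly(A) tail was assumed and not checked here. RNA left uncut at some tRNA genes, each then rising with its neighbours, stays open too, since these 20 genes did not settle that relation (Spearman's rho 0.324, -0.18 to 0.71, permutation p = 0.164, two-sided). Neighbours were taken by gene order without regard to strand, so some need not share a precursor with the tRNA gene. A change in the tails or turnover of mitochondrial rRNA, reads shared with nuclear copies and an effect of the ligand itself were not tested.

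Genes overlapping a gene at least 10 times more abundant on the other strand moved with it. Spearman's rho of the paired log2 changes, across genes, was 0.253 in 831 pairs with shared exonic bases and 0.130 in 416 pairs without. The difference of 0.123 had an interval of 0.005 to 0.243, so close to 0 that its lower bound ranged from 0.001 to 0.008 over 10 runs of 2000 resamples. With 100 or more shared bases required the difference was 0.128 (0.012 to 0.25), and in an earlier run of that version, with the same 2000 resamples, the lower bound lay just under 0. Reads of the abundant gene counted for its partner may account for part of the pattern. MRNIP is not explained by a fixed share of SQSTM1 reads, since its log2 change was larger by 1.47 (SE 0.09), and MRNIP stood at 7.24% of SQSTM1 in DMSO and 20.1% in PhenDC3. Transcription of MRNIP itself and longer SQSTM1 transcripts stay open.

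A fall of genes that span a long stretch of the genome was weak. The median log2 change of 981 protein-coding genes spanning 200 kb or more was lower than that of shorter genes by an amount whose interval reached 0 (difference -0.06, -0.11 to 0.01). After thinning to equal reads it was -0.053 (-0.106 to 0.025), so an effect of the shallower PhenDC3 libraries and a fall in the cells cannot be told apart at this spread. In a linear model the slope per doubling of span was -0.0194 alone and -0.0308 (-0.04 to -0.02) with transcript length, GC content and expression included. These covariates thus did not remove the slope, but its interval treats genes as independent. Spearman's rho of span and log2 change, across genes, was -0.025. Median changes did not fall steadily with span, being -0.036 under 10 kb, -0.008 at 100 to 200 kb and -0.084 at 200 kb or more. The slope therefore cannot decide about a cause. No biological explanation was tested.

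A hypothesis was that PhenDC3 acts on transcripts with a G quadruplex motif near their 5′ end. Of protein-coding genes that rose, 11.4% had a motif in the first 200 transcript bases, against 8.08% of those not called, and the odds ratio with GC content and expression in the model was 1.28 (95% interval 1.09 to 1.49). Of genes that fell, 7.14% had one (odds ratio 0.915, 0.772 to 1.08). On the template strand the odds ratios were 1.02 (0.866 to 1.20) for genes that rose and 1.09 (0.923 to 1.28) for genes that fell. The motif may mark genes that rose, but most of these had none, and annotated transcript starts need not be those used in these cells.

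The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 9818 genes in limma and was the 1 split of the 10 to reach that count. The highest of the others called 0, with 237 genes at an unadjusted p under 0.05 and 0 in edgeR. Every other split put libraries of both treatments in both groups, so the difference between treatments added to the spread within groups. Their lack of calls is therefore no measure of chance.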
